A study of Mus musculus with 6 samples.

How the data were processed

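RNA was measured by sequencing in 6 libraries of 4T1 cells, a mammary carcinoma line from BALB/c mice that here carries a luciferase and a red fluorescent protein. Per the labels, 3 libraries came from the line in culture, and 3 came from cells isolated by fluorescence-activated sorting from mammary gland tumours grown after injection into the milk ducts. The titles of the 3 tumour libraries begin with the word Right, and no title names a left side. Total RNA was extracted with a column kit and libraries were made with a TruSeq RNA kit, per the labels' protocols. Whether that kit kept the strand was not given in the sources used here. Libraries are numbered here 1, 2 and 3 within a group, in the order of the numbers in their labels (6180, 6183 and 6186 for cultured, 6181, 6184 and 6185 for tumour). These label numbers are not shared between the groups, so nothing paired the samples.

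The authors deposited 1 table of log2 values for 13912 genes by gene symbol. Reads were aligned with HISAT to the mouse build mm10, counted per gene with HTSeq and processed with limma, per the submitters' processing notes, which give no versions. The values deposited by the authors were log2 CPM, read counts scaled to the size of the library, in the form that limma's voom function gives, with 0.5 reads added and the library total scaled by the trimmed mean of M-values (TMM). This form was tested on the table. Solving it for reads gave a whole number, within a tolerance of 0.01, in 100% of the cells, and the ratios of scaled to plain library totals multiplied to 1. The smallest total over the 6 libraries was 61 reads, so genes with fewer reads had been left out before deposit. Recovered totals were 39736276, 40680703 and 35448588 reads in cultured libraries 1, 2 and 3, and 39851109, 41469090 and 40323680 reads in tumour libraries 1, 2 and 3. At these totals counting error was small beside the spread between libraries except for genes near 0 reads.

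The groups were compared with limma 3.58.1 in R 4.3.3, on the deposited log2 values, with a variance trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. A change is the tumour mean minus the cultured mean on the log2 scale, and a standard error (SE) is limma's moderated one. Count models, planned as alternatives for deposited or recovered counts, were not run although whole reads were recovered, because the deposited unit is log2, and this departs from the plan. Before use, the fit was tested on simulated reads for 13912 genes, 200 of them changed, with the dispersion set to 0.037. It recovered 73% of the genes changed 2-fold and 100% of those changed 4-fold, all of them with the right direction, with 7 false calls, which was 3.89% of the calls. The list test called the list that had been moved and 0 of 20 unmoved lists. Simulated genes were drawn independently, so this does not show how the list test behaves where members vary together. As many genes were moved up as down, with known library sizes, so the scaling of libraries was not tested either. All simulated genes had the same dispersion, and the changed genes were drawn from those above a minimum of reads. In the data 48.2% of genes changed and the spread differed between genes, so these rates need not carry over.

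A total of 40 gene lists were written before the data were examined, for pathways and for markers of carcinoma, mammary and host cells. The 37 lists with at least 5 tested members were tested with limma's camera, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list, and fry, were alternatives. Genes named in the text followed a rule also fixed before the data were examined. It took the 12 risen and 12 fallen genes with the largest change among those past the threshold whose groups did not overlap and whose higher mean was at least 4 on the log2 CPM scale (16 CPM), leaving out predicted and clone names. It added up to 4 called members of each list with the largest change, or the 2 with the highest mean where none passed, and a preset group of mammary and carcinoma genes. The progesterone receptor gene of that group was not among the genes tested.

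Where a gene had 0 reads in all 3 cultured libraries, its fold is given as a lower bound against a floor of 3 reads over the group. Where it had 1 to 3 reads, the ratio of CPM is given with its 95% counting interval. Intervals and floors cover counting error only, and reads are not independent molecules. Coordinates were taken from GENCODE M21 on GRCm38, the assembly that mm10 names, by gene symbol. Of the 13912 symbols, 13391 (96.3%) matched that annotation, and 481 of the 521 others were found among RefSeq symbols and synonyms. Reads that fit several places, such as those of genes with many processed pseudogenes, can be missing from a table of counts per gene. Gapdh was listed at a mean of -0.34 log2 CPM in culture and Eno1 at 2.22, so values for genes of this kind are uncertain.

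Alternatives fixed before the data were examined were other scalings, a filter on low values, other variance models, library weights, stricter thresholds, leaving out each library and leaving out host marker genes. Alternatives added after the data were seen were voom weights on the recovered reads, median-of-ratios factors, a filter on the cultured mean and scaling to the epithelial list.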

Results

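The transcriptome of 4T1-Luc2-RFP cells was measured in 2 groups of 3 libraries, cells in culture and cells isolated by fluorescence-activated sorting from mammary gland tumours grown in the milk ducts of mice. The 6 libraries held 35448588 to 41469090 reads in 13912 genes. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Only the tumour libraries are labelled as sorted. The correlation of log2 values across genes, which are not independent replicates, was 0.968 to 0.983 between cultured libraries and 0.981 to 0.990 between tumour libraries. Between the groups it was 0.674 to 0.754. The variance between the closest pair of libraries was 7.56 times that of sampling, which does not show whether the libraries are separate samples.

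The comparison asked how the transcriptome of this carcinoma line in the gland differs from that in culture. Marker lists of macrophages, neutrophils and fibroblasts had medians of -3.13, -5.17 and -2.87 log2 CPM in culture and 8.88, 5.36 and 6.23 in the tumour libraries. Lists of G2/M genes and of ribosome biogenesis had medians of 7.16 and 7.85 in culture and 5.95 and 6.79 in the tumour libraries. By limma with Benjamini-Hochberg adjustment at 0.05, 6711 of 13912 genes (48.2%) changed, of which 4099 were higher and 2612 lower in the tumour libraries. A change of at least 2-fold was found in 4526 genes, 3355 higher and 1171 lower. The groups did not overlap in 8325 genes (59.8%), where chance gives 10% for 3 libraries against 3. The share of changed genes that were higher in the tumour libraries was 61.1% as deposited, 48.1% with each library centred on its median, 35.2% after quantile normalization and 86.9% when scaled to the epithelial list. A filter on a cultured mean of at least 1 takes out mainly genes that rose, so its counts, 1791 higher and 2423 lower, follow in part from that selection. The count of lower genes was 1558 without tumour library 1 and 1520 without tumour library 3.

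**Figure D1:**
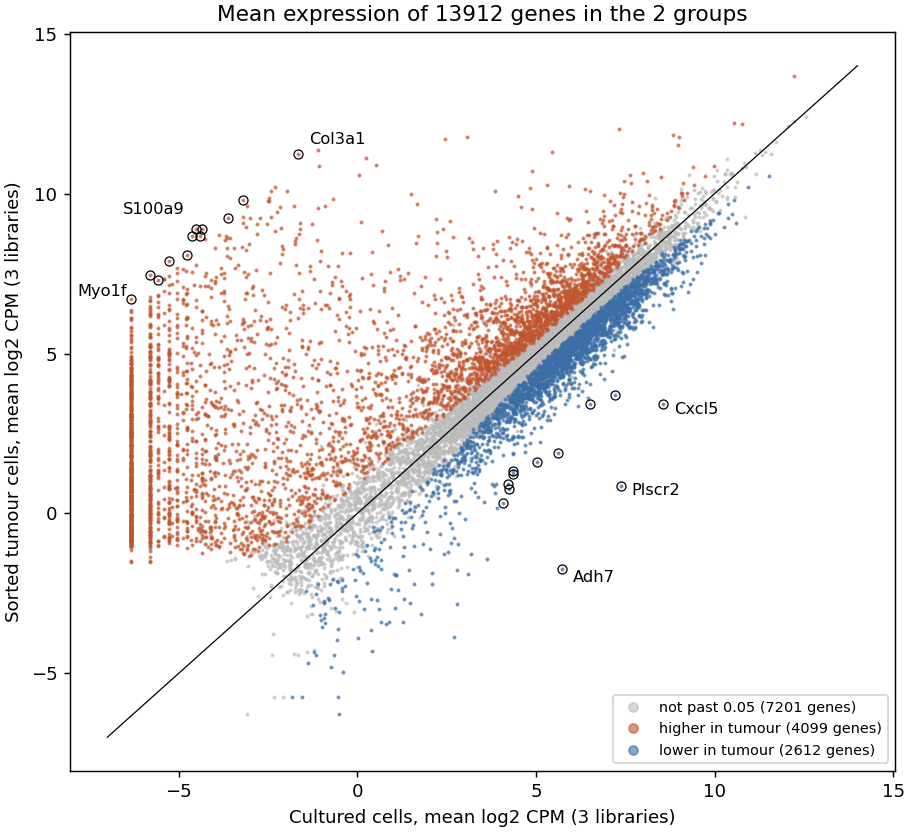
Mean log2 CPM of each of 13912 genes in cultured cells (horizontal) and in sorted tumour cells (vertical), 3 libraries each, with genes past an adjusted p of 0.05 in colour. Rings mark the 12 risen and 12 fallen genes named by rule, and the 4099 higher genes include many with few or 0 reads in culture.

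By the naming rule, the 12 genes with the largest rise were Clec7a, Kctd12, C3ar1, S100a9, Cd83, Trf, Myo1f, Srgn, Col3a1, Itgam, Colec12 and Ccr1. Clec7a, a receptor for fungal glucans on myeloid cells, lies on chromosome 6 from 129461591 to 129472779 of GRCm38 and is annotated as a polymorphic pseudogene. It reached 493 ± 162 CPM (SD, n = 3) in tumour libraries against 8 reads over the 3 cultured libraries. S100a9, which encodes a calcium-binding protein of neutrophils, is a protein-coding gene on chromosome 3 from 90692632 to 90695721. It stood at 751 ± 696 CPM (SD, n = 3) in tumour libraries, with 11 reads in culture. Col3a1, a fibrillar collagen gene on chromosome 1 from 45311538 to 45349706, stood at 2483 ± 691 CPM (SD, n = 3), and Itgam, the integrin alpha M chain of myeloid cells, at 642 ± 228 CPM (SD, n = 3). Myo1f, a myosin of leukocytes on chromosome 17 from 33555707 to 33607764, had 0 reads in culture and was at least 4354-fold higher in tumour libraries. For C3ar1, the receptor of the complement peptide C3a, the ratio over 1 cultured read was 21460 (95% counting interval 3851 to 847700). The ratio over 2 cultured reads was 14750 (4082 to 121800) for Cd83 and 9686 (2681 to 79980) for Colec12.

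By the naming rule, the 12 genes with the largest fall were Adh7, Plscr2, Cxcl5, Gdnf, Klk10, Chac1, Fam71f1, Snx22, Dlk2, Ptpn22, Rnf39 and Reep6. Adh7, an alcohol dehydrogenase on chromosome 3 from 138217760 to 138233382, had a log2 change of -7.48 (SE 0.45, limma adjusted p = 6.67e-06), from a mean of 5.72 to -1.75 log2 CPM. Plscr2, a phospholipid scramblase on chromosome 9 from 92275602 to 92297752, had a change of -6.51 (SE 0.36, limma adjusted p = 4.53e-06). Cxcl5, a chemokine that attracts neutrophils, on chromosome 5 from 90759360 to 90761624, had a change of -5.15 (SE 0.63, limma adjusted p = 0.000359). Changes of the other 9 lay between -3.73 for Gdnf, a neurotrophic factor, and -3.02 for Reep6. The cultured libraries differed widely for some of the 12. Cultured levels were 509 ± 442 CPM for Cxcl5, 218 ± 166 for Chac1, 22.2 ± 19.7 for Gdnf and 30.4 ± 32.9 for Reep6 (SD, n = 3). The spread was smaller for others, such as Plscr2 at 169 ± 44.3 CPM and Ptpn22 at 94.8 ± 29.3 (SD, n = 3). The rule leaves out genes whose higher mean was under 4 log2 CPM, some of which fell further. Btn1a1, at a cultured mean of 2.79, had a change of -4.57 (limma adjusted p = 0.00123).

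Markers of host cells were higher in the tumour libraries for 73 of 78 genes tested and lower for 0, with a median log2 change of 9.59. Genes tested were 6 of 18 listed for lymphocytes, 3 of 10 for adipocytes and 2 of 8 for red cells. Genes with 0 reads in culture, 4 of the 6 for lymphocytes, were in the data only through their tumour reads. The direction of their change was thus fixed. As no deposited gene had under 61 reads over the 6 libraries, this holds also for genes with few cultured reads. Among them were Cd79b with 1 cultured read, Lpl and Pparg with 2 and Csf3r and Fcer1g with 3. The counts of host markers that rose, and the calls of their lists, were thus in part fixed by this filter. The 2814 genes selected for a mean under 1 CPM in culture took 8.49%, 5.31% and 7.96% of the reads of tumour libraries 1, 2 and 3. All 17 macrophage and monocyte markers rose, with a median change of 11.71 (11.70 with genes at 0 reads set to their bound), among them Itgam, Fcer1g and Ptprc, the pan-leukocyte CD45 gene. The same held for 12 of 12 neutrophil markers (median 11.04, 10.82 with bounds), such as S100a9 and Csf3r, and for 14 of 14 fibroblast markers (10.96, 10.86 with bounds), such as Col3a1, Col5a2 and Col1a2. Dendritic cell and MHC class II genes rose in 11 of 12 cases (9.21, 8.93 with bounds), with H2-Aa at 1095 ± 216 CPM (SD, n = 3). Endothelial and pericyte genes rose in 12 of 13 (7.25, 6.71 with bounds), with Pecam1 and Kdr among them. Lymphocyte genes rose in 5 of 6 (6.17, 5.68 with bounds) but stayed at a median of 0.58 log2 CPM, and the T cell gene Cd4 was at 3.03 ± 0.26 CPM (SD, n = 3). After quantile normalization the median change of the lymphocyte list was 1.65 and its call was lost (adjusted p = 0.0618), while that of the endothelial list was 4.65 and the list was called. The 3 adipocyte genes tested rose, Lpl, Pparg and Fabp4, and the red cell genes Alas2 and Slc4a1 did not pass. After quantile normalization both fell, by -3.29 (adjusted p = 0.00166) and -3.71 (adjusted p = 9.37e-05). Adjusted over the list alone, the counts of these lists were the same. Camera called the lists with 5 or more members (adjusted p from 9.20e-12 for macrophages to 0.00653 for lymphocytes). With an estimated correlation the adjusted p was 0.136 for macrophage, dendritic and fibroblast markers, 0.155 for endothelial and lymphocyte markers and 0.312 for neutrophil markers. Neutrophil markers were lower in tumour library 2 than in the other tumour libraries, by a median log2 difference of -2.70. The 95% interval, over markers and not over libraries, was -3.21 to -2.32. Each of 10 markers was lower, those of the 12 in 1 host list alone with a tumour mean of at least 1 log2 CPM. By the same measure tumour library 2 was lower by -0.57 for macrophage markers (16 of 16) and -0.46 for endothelial and pericyte markers (10 of 12). It was lower by -0.40 for dendritic markers (8 of 10) and -0.36 for fibroblast markers (13 of 14). The median of 3 lymphocyte markers was 0.01.

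**Figure D2:**
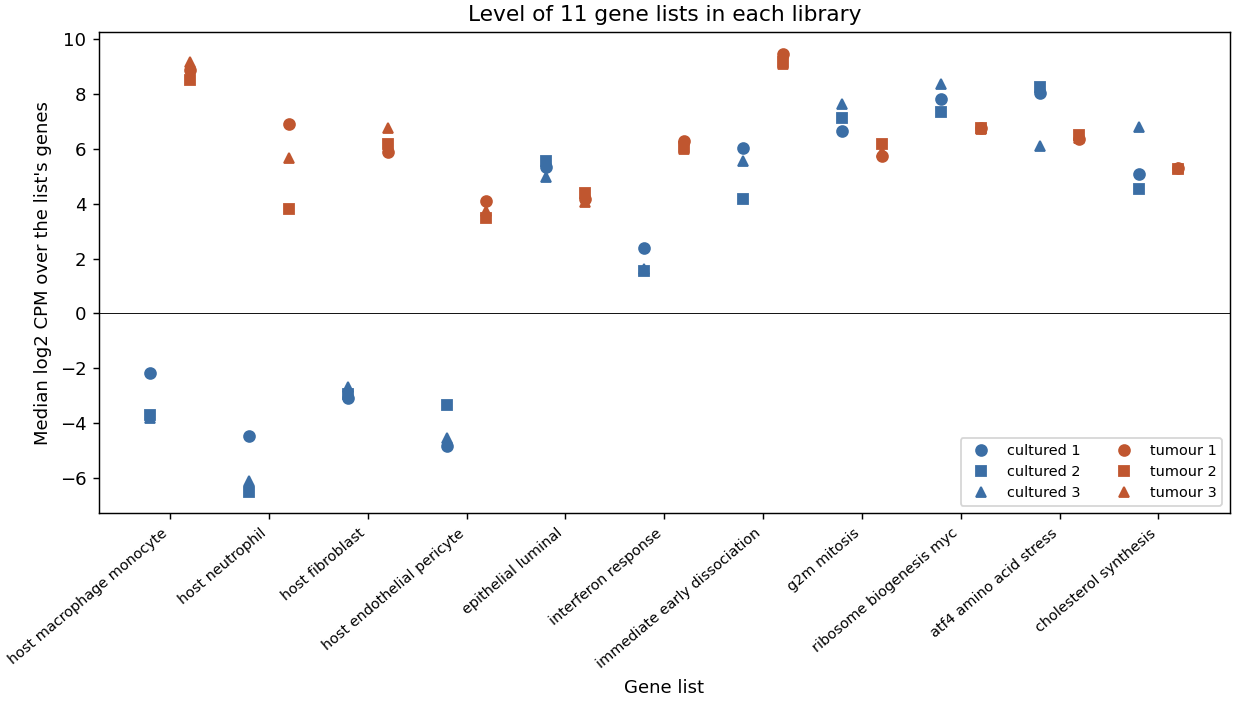
Median log2 CPM over the genes of each of 11 lists, 1 point per library, cultured in blue and tumour in orange. Neutrophil markers stand at 6.89, 3.82 and 5.66 in tumour libraries 1, 2 and 3, and the ATF4 list stands at 6.12 in cultured library 3 against 8.06 and 8.26 in the other cultured libraries.

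Genes of the extracellular matrix and its remodelling rose. Of 28 collagen and matrix genes, 20 rose and 0 fell (21 rose adjusted over the list alone), with a median log2 change of 2.40, and 5 of them also stand in host lists. This list was expressed in both groups, at medians of 7.12 log2 CPM in culture and 9.29 in the tumour libraries. Bgn, a matrix proteoglycan, had a change of 12.24 (SE 0.24). Mesenchymal genes rose in 19 of 20 cases (19 adjusted over the list alone), with a median of 6.27 (5.77 with bounds), including Lox, a collagen cross-linking enzyme, with a change of 11.11, and Postn with 8.15. Vim, the intermediate filament of mesenchymal cells, rose by 1.64 (SE 0.43, limma adjusted p = 0.0148). Its change was 1.62 (limma adjusted p = 0.0521) without tumour library 2 and 1.61 (0.0556) without tumour library 3. Proteases and their regulators rose in 18 of 24 cases and fell in 1, the same adjusted over the list alone, with a median of 3.05. Mmp12, a macrophage elastase, had a change of 11.41 and Mmp2, a gelatinase, one of 8.02. TGF-beta targets rose in 13 of 19 cases (13 adjusted over the list alone), with a median of 1.42, among them Tgfbi with 8.48. Camera gave adjusted p = 8.83e-08 for matrix, 2.97e-08 for mesenchymal, 4.21e-06 for protease and 0.000521 for TGF-beta genes. The adjusted p was 0.0588 with an estimated correlation for matrix and mesenchymal genes and 0.136 for the other lists. Of 11 integrins, Itgb3, Itga1, Itgb5 and Itga5 were among 5 that rose, and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.215, fry adjusted p = 0.000322). The integrin list was called among genes with a cultured mean of at least 1 (camera adjusted p = 0.0156), at an unchanged median of 0.17. That filter takes out mainly genes that rose, so this call can follow from the selection. Fibroblast markers in the same libraries stood at a median of 6.23 log2 CPM, against -2.87 in culture.

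**Figure D3:**
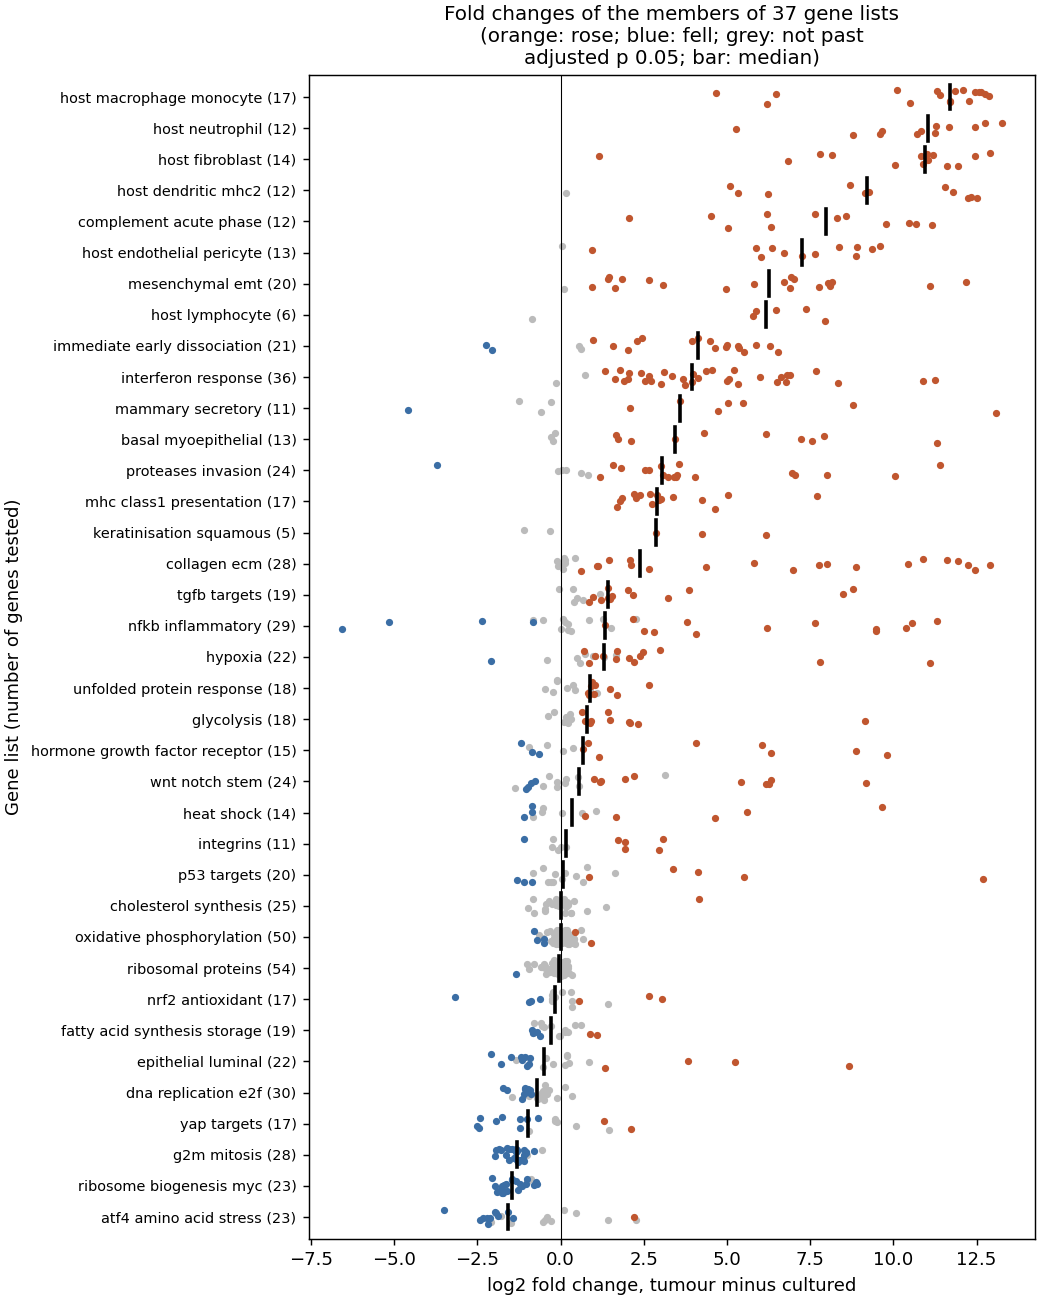
Log2 fold change, tumour minus cultured, of each tested member of the 37 lists with 5 or more members, with the median of each list as a black bar. Medians run from -1.58 for the ATF4 list to 11.71 for macrophage markers.

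Interferon and antigen presentation genes rose nearly throughout. Of 36 interferon response genes, 34 rose and 0 fell (35 rose adjusted over the list alone), with a median change of 3.96, and camera gave adjusted p = 2.49e-10 (adjusted p = 0.343 with an estimated correlation). Iigp1, an interferon-induced GTPase, had a change of 11.26 (SE 0.87), and Cxcl9, a T cell attracting chemokine, one of 10.88 (SE 0.83). All 17 genes of MHC class I presentation rose (17 adjusted over the list alone), with a median of 2.91 and camera adjusted p = 8.83e-08 (adjusted p = 0.185 with an estimated correlation). Psmb9 and Psmb8, subunits of the immunoproteasome, had changes of 7.72 and 4.63, and Tap1, the peptide transporter, one of 5.04 from a cultured mean of 3.25 log2 CPM. All 12 complement and acute phase genes rose (12 adjusted over the list alone), with a median of 7.98 (7.53 with bounds), among them C4b, and camera gave adjusted p = 4.61e-06 (adjusted p = 0.288 with an estimated correlation). Of 29 NF-kB and inflammation genes, 13 rose and 4 fell (the same adjusted over the list alone), with camera adjusted p = 0.109, and the cytokine genes Il1b and Cxcl2 had changes of 10.38 and 10.55. The NF-kB list was called after centring on the median (adjusted p = 0.0423), after quantile normalization (0.00214), without cultured library 1 (0.00296) and by fry (0.0318). Cultured library 3 differed from the other cultured libraries by a median of -1.55 for interferon genes, -1.88 for complement genes, -0.74 for NF-kB genes and -0.61 for MHC class I genes. Macrophage markers in these libraries stood at a median of 8.88 log2 CPM, against -3.13 in culture.

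Immediate early genes, which also respond to tissue dissociation, rose in 17 of 21 cases and fell in 2 (18 and 2 adjusted over the list alone), with a median change of 4.12. Egr1 and Fos, transcription factors of the first minutes of a stimulus, had changes of 6.53 (SE 0.84) and 5.86 (SE 0.88), and Fos reached 2581 ± 610 CPM (SD, n = 3). Camera gave adjusted p = 0.000116, and adjusted p = 0.288 with an estimated correlation. Of 14 heat shock genes, 5 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.998), with a change of 9.67 for the inducible chaperone gene Hspa1a and 4.63 for Hspa1b, near-identical copies between which reads cannot be assigned with certainty. Of 20 p53 targets, 5 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.998). Among them Cdkn1a, a cell cycle inhibitor, had a change of 3.39 (SE 0.40), and Pmaip1, which encodes the pro-apoptotic NOXA, had 0 reads in culture and was at least 3489-fold higher in tumour libraries. The median of the p53 list was 0.086, while camera's direction was down and that of fry was up (fry adjusted p = 0.0167). Of 18 unfolded protein response genes, 9 rose and 0 fell (9 adjusted over the list alone, camera adjusted p = 0.0774), with Dnajb9 at a change of 2.66. This last list was called without cultured library 3 (adjusted p = 0.0134), after quantile normalization (0.00464), with library weights (0.0218) and by fry (0.00812). It was also called among genes with a group mean (0.0437) or a cultured mean (0.000647) of at least 1. The filter on the cultured mean takes out mainly genes that rose, so that call can follow from the selection. The 78 host marker genes tested took 2.82%, 2.10% and 2.83% of reads in tumour libraries 1, 2 and 3. These shares leave out all other genes that host cells express, so they do not measure the share of host RNA.

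Genes of cell division and of ribosome biogenesis were lower in the tumour libraries. Of 28 G2/M genes, 26 fell and 0 rose (28 fell adjusted over the list alone), with a median log2 change of -1.31. Ect2, a regulator of cytokinesis, had a change of -1.98 (SE 0.16), Aurka, a mitotic kinase, one of -1.95 (SE 0.19), and Mki67, the proliferation marker, one of -1.11 (SE 0.23, limma adjusted p = 0.00537). The adjusted p of Mki67 was 0.0525 when libraries were scaled to the epithelial list. Of 30 DNA replication genes, 10 fell and 0 rose (10 adjusted over the list alone), with a median of -0.71, including Pole and Mcm10. Of 23 genes of ribosome biogenesis and MYC targets, 21 fell and 0 rose (23 fell adjusted over the list alone), with a median of -1.47. Myc itself had a change of -2.07 (SE 0.41), Odc1, the first enzyme of polyamine synthesis, one of -1.96 (SE 0.16), and Nop56, a nucleolar protein gene, one of -1.79 (SE 0.15). Of 54 ribosomal protein genes, 53 did not pass and Rpl26 fell, with a median of -0.04 (0 adjusted over the list alone, camera adjusted p = 0.115). That list was called, with a direction of down, after centring on the median (adjusted p = 0.0331), after quantile normalization (0.0431) and without cultured library 1 (0.0158). The call for Rpl26 was lost without tumour library 1 (adjusted p = 0.0773) or 3 (0.102) and when libraries were scaled to the epithelial list (0.109). Camera gave adjusted p = 2.49e-10 for G2/M, 3.13e-05 for replication and 2.24e-09 for ribosome biogenesis, and adjusted p = 0.343, 0.506 and 0.312 with an estimated correlation. The call for replication was lost under fry (adjusted p = 0.103). Cultured library 3 was higher than the other cultured libraries by a median of 1.0 for replication, 0.57 for G2/M and 0.68 for ribosome biogenesis genes. Replication genes stood at medians of 6.17, 6.47 and 7.26 log2 CPM in cultured libraries 1, 2 and 3 and at 5.67, 5.87 and 5.54 in tumour libraries 1, 2 and 3, and without cultured library 3 their median change was -0.33 (adjusted p = 0.00253). Without that library the median change was -1.13 for G2/M and -1.16 for ribosome biogenesis genes. When libraries were scaled to the epithelial list the medians were -0.22 for replication, -0.83 for G2/M and -0.98 for ribosome biogenesis genes. Macrophage and fibroblast markers were at medians of 8.88 and 6.23 log2 CPM in the tumour libraries where these genes were lower.

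Metabolic genes moved in several directions. Of 22 hypoxia genes, 13 rose and 1 fell (the same adjusted over the list alone), with a median change of 1.30 and camera adjusted p = 0.00653 (adjusted p = 0.506 with an estimated correlation). Hypoxia genes stood at medians of 5.86, 6.67 and 5.23 log2 CPM in cultured libraries 1, 2 and 3 and at 7.62, 7.12 and 7.52 in tumour libraries 1, 2 and 3. Cultured library 3 differed from the other cultured libraries by a median of -0.94, and without it the median change was 0.96 (adjusted p = 0.0301). Adm, which encodes adrenomedullin, had a change of 7.80 and Pfkfb3, a regulator of glycolysis, one of 2.98. Of 18 glycolysis genes, 11 rose and 0 fell (11 adjusted over the list alone), with a median of 0.80 and camera adjusted p = 0.0256 (adjusted p = 0.288 with an estimated correlation), among them the glucose transporter gene Slc2a1 with 2.07 and the lactate exporter gene Slc16a3 with 9.15. Of 23 ATF4 and amino acid stress genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -1.58. Psat1 and Psph, of serine synthesis, had changes of -2.34 (SE 0.17) and -2.22 (SE 0.34), and Asns, which makes asparagine, one of -2.44 (SE 0.39). Camera gave adjusted p = 0.000139 for this list, and adjusted p = 0.503 with an estimated correlation, and fry gave adjusted p = 0.105. Its median level was 6.12 log2 CPM in cultured library 3, against 8.06 and 8.26 in the other cultured libraries and 6.37 to 6.51 in tumour libraries. Macrophage markers stood at a median of 8.88 log2 CPM in the tumour libraries for all of these lists.

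Other metabolic lists were not called. Of 50 oxidative phosphorylation genes, 2 rose and 4 fell (0 and 0 adjusted over the list alone), with a median of 0.01 and a camera direction of down (adjusted p = 0.241). Without cultured library 1 its median was -0.09 and the list was called (adjusted p = 0.0486). Of 25 cholesterol synthesis genes, 1 rose and 24 did not pass (1 adjusted over the list alone, camera adjusted p = 0.452, direction down with a median of 0.01). Without cultured library 2 the median was -0.56 and the list was called (adjusted p = 0.0157), and cultured library 3 was higher than the other cultured libraries by a median of 1.93. Of 19 genes of fatty acid synthesis and storage, 2 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.190, and 0.0470 without cultured library 2), with Acaca, the acetyl-CoA carboxylase gene, at -0.86 (-0.38 and adjusted p = 0.0911 when libraries were scaled to the epithelial list). Of 17 NRF2 targets, 3 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.360), with Nqo1, a quinone reductase gene, at -3.18 and Hmox1, which breaks down haem, at 2.66. The median of the NRF2 list was -0.17 and its mean 0.12. Of 4 metallothionein and zinc genes, Mt1 rose by 1.41 and 3 did not pass.

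Epithelial genes were present in both groups. Epcam, the epithelial adhesion gene, stood at 6.63 ± 0.21 log2 CPM (SD, n = 3) in culture and 6.82 ± 0.14 (SD, n = 3) in tumour libraries, a difference of 0.19 as deposited (limma adjusted p = 0.378) and of 0.67 when libraries were scaled to the epithelial list (adjusted p = 0.00982). Krt8, a luminal keratin, stood at 8.89 and 9.74 (limma adjusted p = 0.0970, 0.000620 without cultured library 3, 0.00372 with library weights and 0.0183 when libraries were scaled to the epithelial list). Cdh1, the E-cadherin gene, had a change of -0.91 (SE 0.15, limma adjusted p = 0.00163) and Esrp2, an epithelial splicing regulator, one of -2.08 (SE 0.27). Of 22 luminal epithelial genes, 4 rose and 9 fell (the same adjusted over the list alone). The median of this list was -0.49 and its mean 0.29, and camera gave adjusted p = 0.113. When libraries were scaled to this list, which sets its median to 0 by construction, camera's adjusted p was 0.0226, with a direction of down. Of the 13 basal and myoepithelial genes, 10 rose and 0 fell (10 adjusted over the list alone), with a median of 3.43 and camera adjusted p = 0.000600 (adjusted p = 0.136 with an estimated correlation). Krt14, a basal keratin, rose by 2.13 (SE 0.51), and Acta2 and Tagln, which smooth muscle cells and fibroblasts also express, had changes of 11.32 and 7.55. Cd44, an adhesion receptor, rose by 1.20 (SE 0.23). Endothelial and pericyte markers in the same libraries stood at a median of 3.78 log2 CPM.

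**Figure D4:**
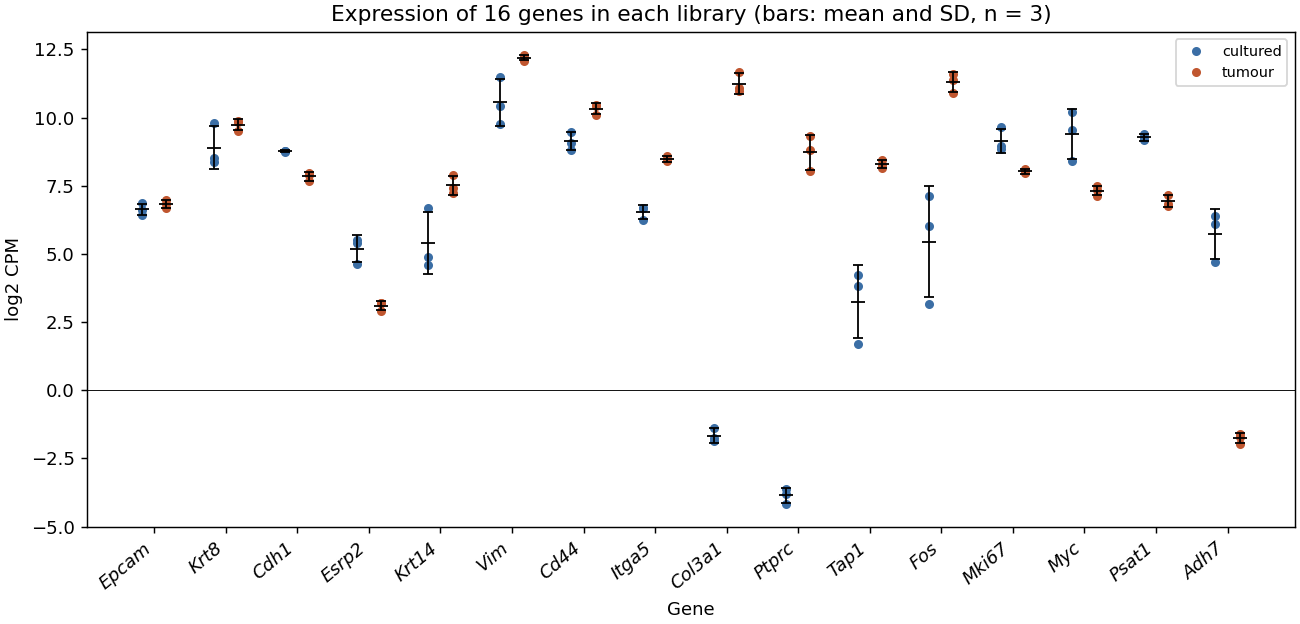
Log2 CPM of 16 genes in each of the 3 cultured (blue) and 3 tumour (orange) libraries, with bars for the mean and SD. Epcam lies at 6.63 and 6.82 on average in culture and tumour, Psat1 at 9.27 and 6.93, and Col3a1 at -1.66 and 11.24.

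Among receptors, Erbb2 stood at 5.82 and 5.42 log2 CPM in culture and tumour (limma adjusted p = 0.228), and Esr1, the oestrogen receptor gene, had a change of 0.82 (SE 0.26, limma adjusted p = 0.0318) that ended under several settings (adjusted p = 0.837 after quantile normalization). Of 15 hormone and growth factor receptors, 8 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.211, fry adjusted p = 0.000126), with Fgfr1 at a change of 9.80. Of 11 genes of mammary secretion, 7 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.136), with a median of 3.58. This list was called after quantile normalization (median 1.83, adjusted p = 0.0480) and by fry (adjusted p = 0.00633), and cultured library 3 differed from the other cultured libraries by a median of -1.62. Trf, the transferrin gene, and Lcn2, a siderophore-binding protein, were among those that rose, and neutrophils also make Lcn2. Ltf, which rose too, also stands in the neutrophil list. Btn1a1 fell by -4.57 (limma adjusted p = 0.00123), and Csn3, at -1.24, did not pass (limma adjusted p = 0.243). The 11 genes tested were part of 19 listed. Of 24 WNT, NOTCH and stem cell genes, 10 rose and 4 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.244, fry adjusted p = 0.000124), with Heyl, a NOTCH target with 0 reads in culture, at least 289-fold higher. Of 5 keratinisation genes, Lgals7, Tgm1 and Krt16 rose (3 adjusted over the list alone, camera adjusted p = 0.243, fry adjusted p = 0.000251). Of 17 YAP targets, 9 fell and 2 rose (9 and 4 adjusted over the list alone), with a median of -0.96 and camera adjusted p = 0.00959 (adjusted p = 0.381 with an estimated correlation). Wwc1, Ajuba and Crim1 had changes of -2.51, -2.44 and -2.42, while Nt5e rose by 2.12. Wwc1 and Ajuba encode regulators of the Hippo pathway itself. The call for this list was lost after quantile normalization (adjusted p = 0.225) and among genes with a cultured mean of at least 1 (adjusted p = 0.0828). Its median was -1.04 in the first of these settings and -0.96 in the second. Host markers in the same libraries had a median change of 9.59.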

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

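The filter on the cultured mean, scaling to the epithelial list, voom weights and median-of-ratios factors were chosen after the data were seen. The edgeR and DESeq2 fits, planned for deposited or recovered counts, were not run although whole reads were recovered, which departs from the plan, and voom weights (6697 genes changed) and median-of-ratios factors (6710) on the recovered reads were run in their place. As deposited, 6711 genes changed, 4099 of them higher and 2612 lower. Lower genes numbered 5513 after quantile normalization and 964 when scaled to the epithelial list, where higher genes numbered 6382. Among genes with a cultured mean of at least 1, 4214 changed, 2180 at least 2-fold and 1791 higher, since this filter takes out genes low in culture, and the lowest correlation within a group was 0.919 against 0.968. The median change over all genes was 0.08 as deposited, -0.14 with each library centred on its median, -0.32 after quantile normalization and 0.57 when scaled to the epithelial list. Leaving out 1 library gave 4821 to 7926 changed genes, 4008 to 4741 changed at least 2-fold, 3301 to 4625 higher, 1520 to 3301 lower, 72 to 73 host markers higher, 22 to 25 lists called and a lowest correlation of 0.968 to 0.981. Lower genes were 1558 without tumour library 1 and 1520 without tumour library 3, with fewer samples in the fit. Of 37 lists, 22 were called with the preset correlation, 0 with an estimated one (10 at an unadjusted p under 0.05, lowest adjusted p 0.0588) and 28 by fry, which does not compare a list with other genes. Where a gene was called as deposited or under the alternative, sign changed only for Alas2 (-3.29) and Atp5l (-0.62), after quantile normalization. Under the same condition the direction of the test changed for the p53 list under fry (median 0.086 in both, fry adjusted p = 0.0167). The cause of these changes was not tested. List medians turned sign in 32 cases over 9 lists, none of them called as deposited, and 2 of these cases were called, oxidative phosphorylation without cultured library 1 (-0.09) and cholesterol synthesis without cultured library 2 (-0.56). Over all alternatives, named genes kept their side of the threshold in 2676 cases, lost the call in 60 and gained it in 5. In 2 cases the sign changed with a call as deposited or under the alternative. For lists, by the direction of the test, these numbers were 667, 27, 24 and 1. A change of sign with no call in either fit is counted among the cases that kept their side. Depth limits genes near 0 reads in culture, whose folds are bounds or wide intervals.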

Other observations

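Families of genes with a shared symbol stem, chosen after the data were seen, were tested with camera over 227 families of at least 8 members. The counts given are of single genes called at an adjusted p below 0.05. C-type lectin genes (Clec), receptors largely of myeloid cells, rose in 18 of 20 cases with a median log2 change of 7.31, and all 11 Toll-like receptor genes (Tlr), sensors of microbial molecules, rose with a median of 6.78. The clustered protocadherin beta genes (Pcdhb), cell adhesion proteins best known from neurons, rose in 12 of 13 cases with a median of 3.03 as deposited and -0.03 after quantile normalization, where the sign turned, and as near-identical copies their reads are uncertain. Nucleoporin genes (Nup), which build the nuclear pore, fell in 15 of 21 cases with a median of -1.03. Genes named Rad, many of them of DNA repair, fell in 15 of 18 cases with a median of -0.90, and mitochondrial ribosomal protein genes (Mrpl) in 15 of 48 with a median of -0.42 as deposited and 0.07 when scaled to the epithelial list, where the sign turned. The medians of the Clec, Tlr, Nup and Rad families kept their sign under centring, quantile normalization and scaling to the epithelial list, where Nup stood at -0.54 and Rad at -0.41. Camera's adjusted p was 1.28e-06 for Clec, 3.15e-05 for Tlr, 0.000904 for Pcdhb, 1.92e-05 for Nup and Rad and 0.00129 for Mrpl. With an estimated correlation the adjusted p was 0.610 for Clec, Tlr and Rad, 0.679 for Nup, 0.696 for Pcdhb and 0.796 for Mrpl.

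Cultured library 3 stood apart from the other cultured libraries. Its cholesterol synthesis genes were higher by a median log2 difference of 1.93 and its DNA replication genes by 1.0, while complement genes differed by -1.88, ATF4 and amino acid stress genes by -1.70 and interferon genes by -1.55. Among 10000 random lists matched on expression, these medians lay at percentile 100 for cholesterol synthesis and replication and at percentile 0 for the other lists. This describes 1 library and is no test of a condition.

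Of the tests that follow, those of host cells in the sorted fraction, of depth, of dilution, of a difference between cultures and of scaling for the mitosis and ribosome lists were chosen after the result was seen, and the criterion for dilution was made stricter after its first result was seen. The 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split gave 6711 changed genes and 4526 changed at least 2-fold. The highest of the other splits gave 0 in both counts, which left 1 split, the real one, at that count. Each of the other splits mixes the groups on both sides, so the difference between groups counts there as spread. Their counts therefore say nothing about chance.

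Host marker genes were higher in the tumour libraries, with a median log2 change of 9.59. Scaling as the whole cause is argued against by the lowest median under another scaling, 7.19. Depth is argued against by a ratio of mean total reads, cultured to tumour, of 0.953. Macrophage and fibroblast markers stood at a median of 8.72 log2 CPM in the tumour libraries. Macrophage, neutrophil and endothelial and pericyte lists stood at medians of 8.88, 5.36 and 3.78 log2 CPM in the same tumour libraries. Expression in the carcinoma cells alone would require 1 line to express markers of all these cell types at once. These levels argue against it as the only source of these lists. For a single gene, host cells or their RNA and expression in the carcinoma cells cannot be told apart, because both would give such levels. Only the tumour libraries are labelled as sorted, by a gate not given in the sources used here.

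Mitosis and ribosome biogenesis genes were lower in the tumour libraries, with a median of -1.34 over both lists. If host RNA had only diluted carcinoma RNA, they would have fallen as the epithelial list did. By the median change over genes they fell further, by -0.85 (95% interval over genes -1.59 to -0.25). That list's own median and mean differ in sign, and it holds Kit and Prom1, which rose from 1 and 2 reads in culture. Its median level went from 5.35 log2 CPM in culture to 4.27 in the tumour libraries. Those of G2/M and ribosome biogenesis went from 7.16 to 5.95 and from 7.85 to 6.79. By level the lists fell by similar amounts, so this yardstick cannot decide on dilution. The medians over both lists were -1.56 (95% interval over genes -1.69 to -1.43) with each library centred on its median and -1.40 (-1.65 to -1.34) after quantile normalization. Both settings moved the median change over all genes down, from 0.08 to -0.14 and -0.32, so they do not decide on scaling. The highest median over both lists was the one scaled to the epithelial list, -0.85, so part of the fall depends on the scaling. That value repeats the comparison with the epithelial list above, so scaling as the whole cause stays open. The rates of division of carcinoma cells and of host cells in the fraction were not tested.

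ATF4 and amino acid stress genes were lower in the tumour libraries against the mean of the cultures. For cultured library 3 the median over genes of its difference from the tumour mean was 0.24, against 2.0 for the other cultured libraries. The 95% interval of 0.24, over genes and not over cultures, lay on both sides of 0 (-0.62 to 1.40). The median level of cultured library 3, 6.12 log2 CPM, lay below those of the tumour libraries (6.37 to 6.51). A difference between the cultures, such as in the state of the medium, cannot be told apart from a difference between gland and culture, because the interval is wide and 1 culture departs from the others. A version of this test on the 11 genes that fell was tried and left out, since genes called across all cultures are above the tumour level in cultured library 3 by their selection. Dilution by host RNA also stays open, since the list fell by -1.10 relative to the epithelial list with an interval over genes from -2.06 to 0.44.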
